A study of Mus musculus with 212 samples.

How the data were processed

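Single cells from differentiating mouse ES cells (embryoid bodies), embryos and neonatal and adult hearts were sorted into strips, lysed and reverse transcribed with a direct one-step kit, pre-amplified with TaqMan assays and quantified on Fluidigm chips in a BioMark instrument, per the labels' protocols. The authors deposited quantification cycles (Ct) for 42 assays in 7 tables; lower Ct means more template, and 25 is the value of an assay without signal, as the values show. Neither a reference-gene correction nor a removal of cells is recorded in the labels, and the Ct threshold, the quality filter and the number of cycles are not given in the sources used here. The values vary freely for Actb, the one housekeeping assay, so they are not relative to it. Because Ct ends at 25, a weakly expressed gene and an absent one read alike, and differences against an undetected group are lower limits in size.

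Samples were grouped by the table their description names, and within tables by the cell names in the tables' second line. The titles of 2 sets name the opposite origin to their table (D5-D8 and E7.5-E10.5), and those of the D23-D29 set another stage. Each of 6 tables also holds a negative and a positive control column (12 in all), which were used as controls and not as cells; the E10.5 table holds none. The negative controls gave no signal on any assay. The positive control was identical in the reference, D5-D8 and E7.5-E10.5 tables, and differed in the D23-D29 table. Of its values in the atrial and in the ventricular table, 40 stood 1 row lower than in the other tables. The cells of these 2 tables did not follow that shift: over 5 genes with a pair of assays, the mean absolute difference between the assays was 1.13 and 1.40 cycles with the row names as given, and 9.49 and 7.25 with names shifted by 1 row. Row names were therefore kept.

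Expression was computed as 25 minus Ct, and an undetected assay counted as 0. For each set and assay the mean over all cells, the SD between cells and the share of cells detecting the assay were computed, with exact (Clopper-Pearson) 95% intervals that cover counting error only. Differences of means are on the cycle (log2) scale. The labels name no animal or culture, so no test, p-value or standard error was computed. Precision is limited by the number of cells, 5 to 72 per named set, and by the detection limit. Of the 200 cells, 8 repeat another table's cell in all 42 values, which leaves 192 distinct cells. The 6 that recur between the E tables were left out of the E10.5 table in its comparison, and in the assignment a cell's own copy was left out of the CM reference mean.

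Named assays followed a rule fixed before the data were examined: for each comparison, the 12 assays with the largest positive and the 12 with the largest negative difference among those of at least 1 cycle, and any assay whose detection share differed by at least 50 percentage points. Other assays are named as members of marker lists, which were fixed at the same time for cardiomyocytes (10 assays here), atrial (2) and ventricular (4) cardiomyocytes, conduction (1), smooth muscle (3), endothelium and endocardium (4), fibroblasts (3), cardiac progenitors and transcription factors (15), pluripotency (2) and housekeeping (1); the lists for epicardium, blood and cell cycle have 0 assays here. Lists overlap. Single assays named only in the accounts of days, stages and reference types to show an order were chosen after their values were seen. Gene names are those of the tables, with 3 exceptions. Calponin 1 and Calponin 2 were read as Cnn1 and Cnn2, and Myh11-1 and Myh11-2 as 1 assay, Myh11. Of the assays, 38 matched a current symbol of the RefSeq annotation of GRCm38.p6 and 4 a synonym (Flk-1 is Kdr, Nkx2.5 is Nkx2-5). Sm22A fits 2 symbols, Tagln and Tagln2, and was counted as Tagln. For 9 genes there are 2 assays, given with their numbers.

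Cells were assigned to the reference type with the highest Pearson correlation to the type's mean over the assays other than Actb. Co-detection is the share of cells with at least 1 detected assay of each of 2 lists. The alternatives planned before the data were examined were centring each cell on Actb or on the median detected assay (undetected values then take the lowest centred value of the cells compared), a detection limit 2 cycles stricter (Ct 23), means over detecting cells (at least 3 per set), medians over cells, a filter on cells (Actb undetected, or detected assays more than 3 median absolute deviations below the table's median, which left out 2 cells of the E7.5-E10.5 table, 3 of the E10.5 table and 1 of the ventricular table), Spearman correlation, Euclidean distance or detection alone for the assignment, and 2 assays per list for co-detection. Added after the data were seen were single stages or ages, all 72 E10.5 cells, a CM reference without the 2 repeated cells, and values relative to the positive control. The difference step was tested on simulated data: with 10 of 42 assays changed by 3 cycles between simulated atrial and ventricular cells, all 10 had the right sign and at least 1 cycle in the mean over 100 rounds, and 0 of the others reached 1 cycle. Simulated levels were raised by 3 cycles, and detection did not depend on level, so the detection limit was not tested. Nor does a mean over 100 rounds show how often a single comparison passes 1 cycle by chance. The assignment step was tested on 120 cells simulated around the means of the 6 reference types over 41 assays, and 100% returned to their type. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.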

Results

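Expression of 33 genes was measured with 42 TaqMan assays by microfluidic quantitative PCR in single cells of the mouse cardiovascular lineages, from differentiating embryonic stem (ES) cell cultures, embryos and hearts. Deposited values are quantification cycles (Ct), and an assay without signal is listed at 25. Expression is given here as 25 minus Ct, in cycles above this detection limit, where 1 cycle is 1 unit on the log2 scale at full PCR efficiency and 0 stands for not detected. The 7 tables held 200 cells and 12 control columns. A set of 30 reference cells comprised 6 types of 5 cells each, which the cell names call CPC, CM, SMC, FB, EDC and ES. There were 24 cells in the D5-D8 table (6 per day), 20 in the D23-D29 table (10 per day), 24 in the E7.5-E10.5 table (6 per stage) and 72 in the E10.5 table. The atrial and the ventricular table held 15 cells each, 5 neonatal and 10 adult. Cells detected 8.20 ± 1.30 (SD, n = 5) assays in the ES reference cells, the fewest of any named set, and 29.5 ± 2.35 (SD, n = 6) in the E9.5 cells, the most.

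For 3 sets the sample titles contradict the table names. The D5-D8 cells are titled as embryo cells and the E7.5-E10.5 cells as late ES-derived cells, which is the opposite origin, and the D23-D29 cells are titled as ES-derived cells of early stages. The names of the cells inside the tables follow the table names, so sets are called by table and cell name throughout. No label names an animal or a culture, so each set of cells is 1 sample, no difference could be tested against the spread between animals or cultures, and the SD given is the spread between cells. Intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only. Cells that occur in 2 tables with identical values in all 42 assays were counted once in a comparison. These were the 6 E10.5 cells of the E7.5-E10.5 table, which recur in the E10.5 table, and 2 CM reference cells, which recur as D29 cells.

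**Figure D1:**
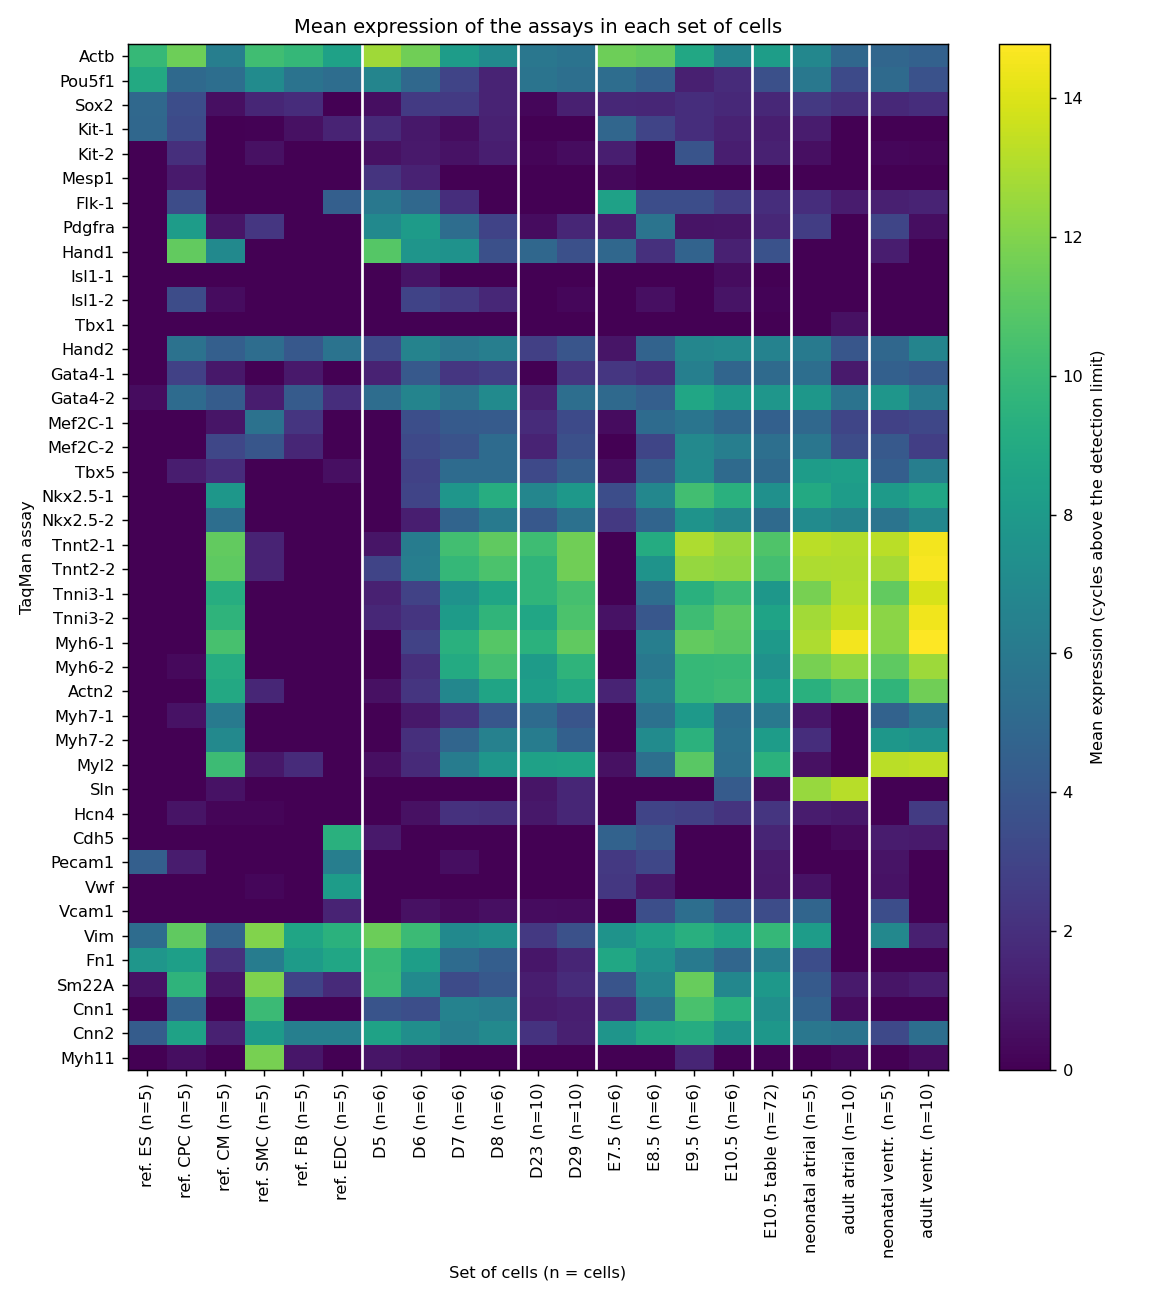
Mean expression of the 42 assays (rows; colour, cycles above the detection limit) in each set of cells (columns; n, number of cells), with white lines between tables. Tnnt2-1 had a mean of 0.85 in D5 cells and 11.18 in D8 cells, and Sln had a mean of 13.21 in adult atrial cells and 0 in adult ventricular cells.

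The reference cells asked which assays mark each cell type. The CM cells carried the contractile genes: Tnnt2-1, the assay of cardiac troponin T, was at 11.24 ± 1.18 cycles, Myh6-1 (alpha myosin heavy chain) at 10.47 ± 0.80 and Myl2 (ventricular regulatory light chain) at 10.16 ± 0.65 (SD, n = 5 each). Myh6-1, Myh7-2, Nkx2.5-2, Tnni3-1 and Tnni3-2 were detected in all 5 CM cells and in 0 of the 25 other reference cells. The SMC cells carried Myh11, smooth muscle myosin, at 11.75 ± 0.70, Sm22A, an actin-binding smooth muscle protein, at 11.91 ± 1.11 and Cnn1 (calponin) at 10.08 ± 0.90 (SD, n = 5 each). The EDC cells carried the endothelial genes Cdh5 (VE-cadherin) at 9.35 ± 1.03, Vwf (von Willebrand factor) at 8.20 ± 1.70 and Pecam1 at 6.30 ± 0.74 (SD, n = 5 each). Cdh5 was detected in all 5 EDC cells and in 0 of the 25 others.

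CPC cells carried Hand1, a transcription factor of early cardiac mesoderm, at 11.22 ± 1.19, and Pdgfra, a mesodermal receptor, at 8.16 ± 0.83 (SD, n = 5 each). Hand1 was also detected in all 5 CM cells, at 7.0 ± 0.46. Isl1-2, an assay of the progenitor factor Isl1, was detected in 4 of 5 CPC cells with a mean of 3.41 ± 2.10, while Isl1-1 was detected in 0 of 5. The ES cells had the highest mean of the pluripotency factor Pou5f1, 8.99 ± 0.65 (SD, n = 5), against 5.06 ± 1.79 to 7.14 ± 0.60 in the other types, and Sox2 was detected in all 5 at a mean of 5.02 ± 1.39. FB cells shared Vim at 8.71 ± 0.98 and Fn1 at 8.12 ± 0.61 with other types, and no assay was detected in all FB cells and in no other reference cell, as was the case for CPC, SMC and ES cells. Vim averaged more in SMC (11.99 ± 0.56) and CPC cells (11.20 ± 0.53). Pdgfra, also on the fibroblast list, was detected in 0 of 5 FB cells. Counts of that list are therefore not specific to the FB type. Against the mean of the other types, 17 assays were at least 1 cycle higher (11 after centring on Actb) and 18 at least 1 cycle lower in CPC, 16 and 15 in CM, 10 and 16 in SMC, 3 and 21 in FB, 8 and 23 in EDC, and 5 and 26 in ES cells.

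The comparison of chambers asked which assays separate atrial from ventricular cells. Sln (sarcolipin, a regulator of the calcium pump of atrial muscle) was detected in 15 of 15 atrial cells at 12.98 ± 0.66 cycles (SD, n = 15) and in 0 of 15 ventricular cells, which allows a share of up to 21.8%. Myl2 was the mirror image, at 13.33 ± 1.15 in 15 of 15 ventricular cells and 0.23 ± 0.88 in atrial cells, where 1 of 15 detected it. Myh7, the slow myosin heavy chain, was also a ventricular assay: Myh7-2 averaged 7.62 ± 4.76 in ventricular cells (detected in 12 of 15) and 0.64 ± 1.70 in atrial cells (2 of 15), and Myh7-1 averaged 5.42 ± 4.42 and 0.29 ± 1.14. Tbx5, a T-box factor, was detected in every cell of both tables and averaged 8.26 ± 1.04 in atrial and 5.70 ± 1.40 in ventricular cells, a difference of 2.57 cycles.

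The pan-cardiomyocyte assays differed less. Myh6-1 averaged 13.99 ± 1.09 in atrial and 13.90 ± 1.64 in ventricular cells, Tnni3-2 (cardiac troponin I) 13.20 ± 0.82 and 13.70 ± 1.43, and Tnnt2-2 12.99 ± 0.80 and 14.01 ± 1.26. Of the 10 assays of the cardiomyocyte list, 0 were at least 1 cycle higher in atrial cells, 4 were at least 1 cycle lower (6 on either centring) and 6 lay within 1 cycle. Those 4 were Myl2, both Myh7 assays and Tnnt2-2. Both assays of the atrial list, Sln and Tbx5, were higher in atrial cells, and 3 of the 4 of the ventricular list were lower. Gata4-1 averaged 2.48 ± 2.96 in atrial and 4.27 ± 2.02 in ventricular cells, and Hand2 4.66 ± 1.97 and 6.12 ± 1.46. Gata4-2, the other assay of Gata4, lay within 1 cycle, at 6.38 ± 2.07 and 6.73 ± 2.10. The other assays at least 1 cycle higher in atrial cells had atrial SDs above their differences: Cnn1 (1.88 ± 2.83 against 0), Fn1 (1.17 ± 3.05 against 0), Cnn2 (5.70 ± 1.23 against 4.64 ± 3.09), Sm22A (2.11 ± 3.53 against 1.05 ± 1.63) and Mef2C-2 (4.24 ± 2.30 against 3.19 ± 2.73). These differences were larger in neonatal cells: in adult cells alone, uncentred, all 5 lay within 1 cycle, with Cnn1 at 0.51 and Fn1 at 0 (detected in 0 of 10 atrial cells), against 4.64 and 3.52 in neonatal cells. Neonatal atrial Fn1 was uneven, with an SD of 4.71 and a median of 3.80 over the 3 of 5 cells detecting it. Mef2C-2 turned this order on centring, at 1.05 in adult and 0.41 in neonatal cells on Actb and 1.38 and 1.24 on the median detected assay. With the ages pooled, the 4 endothelial assays lay within 1 cycle (1 of them was lower after centring each cell on its median detected assay), as did Pou5f1 and Sox2. Hcn4 did so (0.99 against 1.70) only because the ages differed in direction, with -1.62 in adult and 1.10 in neonatal cells, and Cdh5 was at -1.15 in neonatal cells. The neonatal values rest on few cells, since Hcn4 was detected in 2 of 5 atrial and Cdh5 in 1 of 5 ventricular cells. Neonatal Hcn4 was at 0.94 on Actb and 0.59 on the median detected assay.

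In all, 7 assays were at least 1 cycle higher and 6 at least 1 cycle lower in atrial cells. Centring each cell on Actb, which shifted the median assay by -0.39, gave 5 and 10, and centring on the median detected assay, a shift of -0.17, gave 7 and 9. Means over detecting cells alone gave 4 and 2 and turned Cnn2 (-0.62), Mef2C-2 (-0.76) and Gata4-1 (0.395), and both medians over cells and a limit 2 cycles stricter gave 3 higher. Adult cells alone gave 2 and 10. Neonatal cells alone gave 15 and 5, which became 7 and 18 on Actb and 9 and 6 on the median. Among uncentred neonatal cells Gata4-1, Hand2 and Tnnt2-2 were higher in the atrial ones, by 0.80, 1.15 and 0.21 cycles, which centring on Actb turned to -1.13, -0.78 and -1.71. Sln and Myl2 kept differences of 13.21 and -13.36 in adult and 12.52 and -12.58 in neonatal cells.

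**Figure D2:**
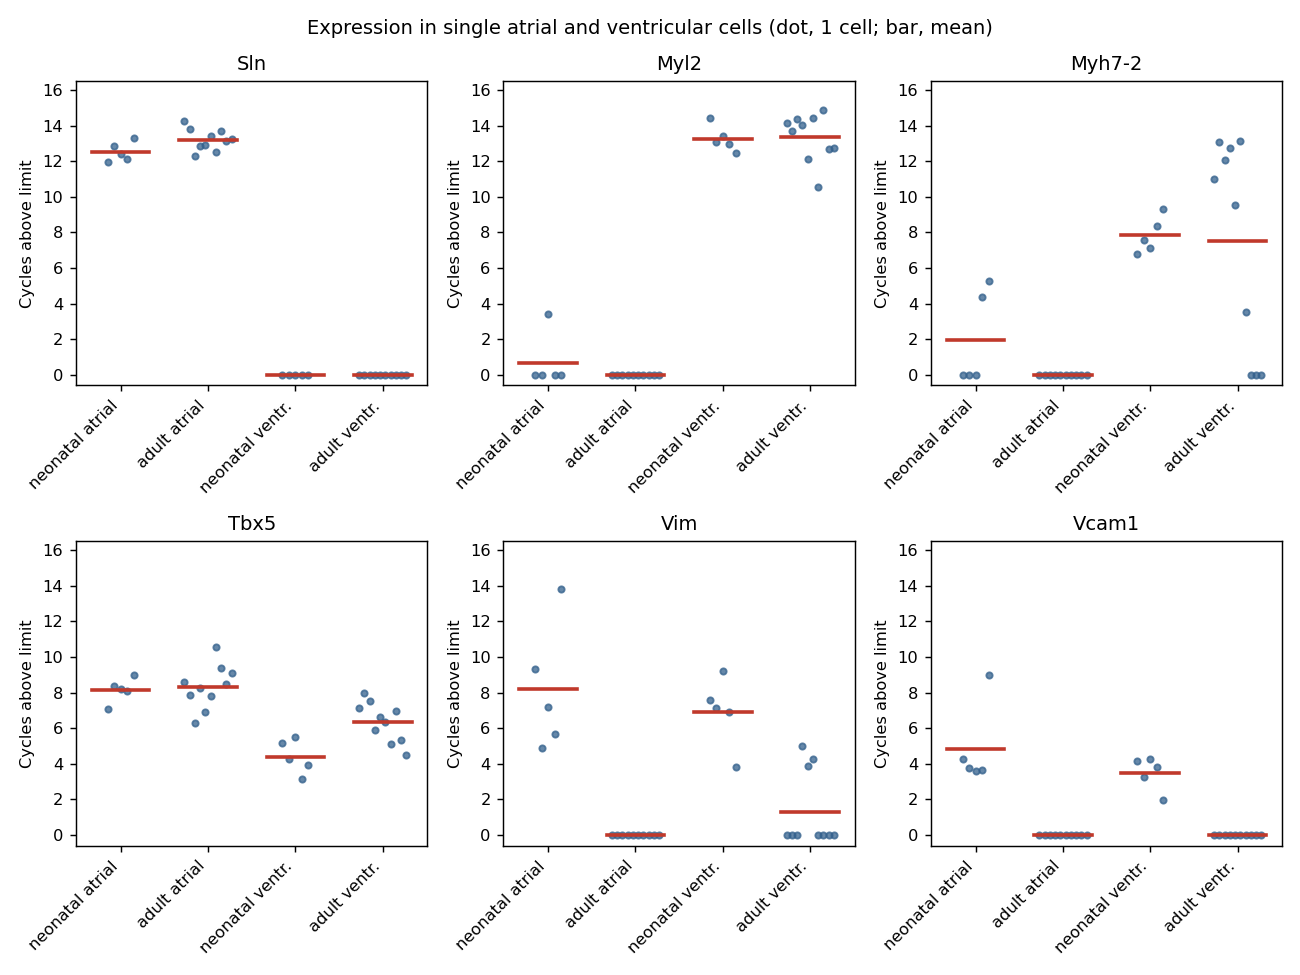
Expression (cycles above the detection limit) of Sln, Myl2, Myh7-2, Tbx5, Vim and Vcam1 in single neonatal and adult atrial and ventricular cells; each dot is 1 cell and each bar the mean. Sln and Myl2 separated the chambers, and Vcam1 was detected in all 10 neonatal and in 0 of the 20 adult cells.

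Age differed within each chamber. Vim, an intermediate filament protein, averaged 8.18 ± 3.56 in neonatal atrial cells (n = 5) and was detected in 0 of 10 adult atrial cells. In the ventricle it averaged 6.92 ± 1.96 (n = 5) and 1.32 ± 2.14 (n = 10). Vcam1, an adhesion molecule, was detected in all 5 neonatal cells of each chamber (4.85 ± 2.33 atrial, 3.49 ± 0.94 ventricular) and in 0 of 10 adult cells of each, which allows a share of up to 30.8%. Contractile assays were higher in adult ventricular cells as measured: Tnni3-1 averaged 13.88 ± 1.05 against 11.21 ± 0.50, Myh6-1 14.78 ± 1.13 against 12.14 ± 0.86 and Actn2 (alpha-actinin) 11.57 ± 1.42 against 9.67 ± 0.71. In atria Tnni3-1 averaged 13.05 ± 0.55 in adult and 11.73 ± 0.53 in neonatal cells.

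Among the 10 cardiomyocyte assays, 8 were at least 1 cycle higher in adult than in neonatal ventricular cells, but 2 were higher and 2 lower after centring on the median detected assay. In adult atrial cells 3 were higher and 1 lower, with 7 and 3 on Actb and 1 and 3 on the median. All 3 fibroblast assays (Fn1, Pdgfra, Vim) were at least 1 cycle lower in adult atrial cells, and 2 of the 3 in adult ventricular cells. Gata4-1 averaged 5.33 ± 1.68 in neonatal and 1.06 ± 2.38 in adult atrial cells, and Cnn1 4.64 ± 2.83 and 0.51 ± 1.60. The other Gata4 assay, Gata4-2, was detected in all of these cells, at 7.85 ± 1.04 in neonatal and 5.64 ± 2.10 in adult ones. In all, 3 assays were at least 1 cycle higher and 15 lower in adult atrial cells, and 13 and 7 in adult ventricular cells. Centring changed these splits. In atrial cells it gave 13 and 13 on Actb and 1 and 22 on the median detected assay, with shifts of 0.60 and -0.52 in the median assay. In ventricular cells the median gave 3 and 11, with shifts of -1.01 on the median and -0.23 on Actb.

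The days within the D5-D8 table set cells of D5 to D8 in order. Of the 10 cardiomyocyte assays 8 were at least 1 cycle higher on D6 than on D5, all 10 on D7 than on D6 and 8 on D8 than on D7 (7 after centring on the median detected assay), and the others lay within 1 cycle. Much of the last step was detection. Over the 5 of 6 D7 cells detecting them, Myh6-1 averaged 11.23, Tnni3-1 9.04 and Actn2 8.21 cycles, against 10.86, 8.71 and 8.63 on D8. Both Myh7 assays stayed higher on D8 in detecting cells (Myh7-1 4.38 and 6.05, Myh7-2 5.80 and 7.80). On D6, Myh6-2 and Myl2 were each detected in 1 of 6 cells. Tnnt2-1 averaged 0.85 ± 2.09, 6.19 ± 4.30, 10.33 ± 2.33 and 11.18 ± 1.09 cycles on D5, D6, D7 and D8 (SD, n = 6 per day). Myh6-1 was detected in 0, 2, 5 and 6 of 6 cells and Nkx2.5-1, a cardiac homeobox factor, in 0, 2, 5 and 6. Hand1, Flk-1 and Mesp1 ran the other way. Hand1 averaged 10.88 ± 2.23 on D5 and 3.58 ± 4.33 on D8, Flk-1 (the receptor Kdr) 5.89 ± 3.44 and 0, and Mesp1, a factor of nascent cardiac mesoderm, was detected in 3, 2, 0 and 0 cells. Isl1-2 was detected in 0, 5, 4 and 2 cells, with its highest mean on D6 (2.95 ± 1.73).

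From D5 to D8 all 10 cardiomyocyte assays were at least 1 cycle higher, with a median difference of 7.76 cycles. All 3 fibroblast assays were lower as measured, but after centring on Actb 1 (Vim) was higher and 0 lower. Actb itself differed by -5.57 cycles. Centred on the median detected assay, Vim (-3.82), Fn1 (-5.26) and Pdgfra (-3.88) all stayed lower. Among the 15 assays of progenitor and transcription factors, 9 were higher and 4 lower (Flk-1, Hand1, Mesp1 and Pdgfra). On Actb these were 9 and 2, with Mesp1 (-0.85) and Pdgfra (-0.42) within 1 cycle. Mesp1 was at -2.14 on the median detected assay. Pou5f1 averaged 6.75 ± 1.27 on D5 and 1.46 ± 1.64 on D8, and Sm22A 10.07 ± 0.96 and 4.06 ± 3.17. These differences were -1.30 and -1.29 relative to Actb, and -5.18 and -5.99 on the median detected assay. The housekeeping assay Actb itself averaged 12.66 ± 0.46 and 7.09 ± 1.59. In all, 21 assays were higher and 11 lower on D8, and 26 and 4 after centring on Actb, which shifted the median assay by 2.84. Centring on the median detected assay gave 21 and 10.

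In the E7.5-E10.5 table the contractile assays were low at the first stage. Tnnt2-1 was detected in 0 of 6 cells at E7.5 and averaged 9.08 ± 5.43, 12.96 ± 0.58 and 12.42 ± 0.86 at E8.5, E9.5 and E10.5 (SD, n = 6 per stage). Flk-1 and Cdh5 had their highest means at E7.5: Flk-1 averaged 8.45 ± 4.18 at E7.5 and 2.63 ± 3.0 at E10.5, and Cdh5 was detected in 3, 2, 0 and 0 cells. The 0 of Cdh5 at E10.5 rests on 6 cells. In the 66 other cells of the E10.5 table, Cdh5, Pecam1 and Vwf were detected together in 7. Cnn1 averaged 1.85 ± 2.90 at E7.5 and 9.36 ± 1.07 at E10.5, and Sm22A reached its highest mean at E9.5 (11.35 ± 1.17). Myl2 averaged 11.01 ± 1.73 at E9.5 and 5.38 ± 6.45 at E10.5, when 3 of 6 cells detected it and 4 of 6 detected Sln. Both values rest on these 6 cells, since in the 66 other cells of the E10.5 table Myl2 averaged 9.78 ± 5.14 and was detected in 56, and Sln was detected in 1.

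From E7.5 to E10.5 all 10 cardiomyocyte assays were at least 1 cycle higher (median difference 10.06 cycles), all 4 endothelial assays were lower, and of the 3 smooth muscle assays 2 were higher (Cnn1, Sm22A). Actb averaged 11.50 ± 0.72 at E7.5 and 6.70 ± 1.06 at E10.5. In all, 24 assays were higher and 9 lower, and centring shifted the median assay by 3.30 (Actb) and -0.74 (median detected assay). From E9.5 to E10.5, 1 assay (Sln) was at least 1 cycle higher and 14 were lower, and centring turned this split to 18 and 6 on Actb and 6 and 8 on the median.

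**Figure D3:**
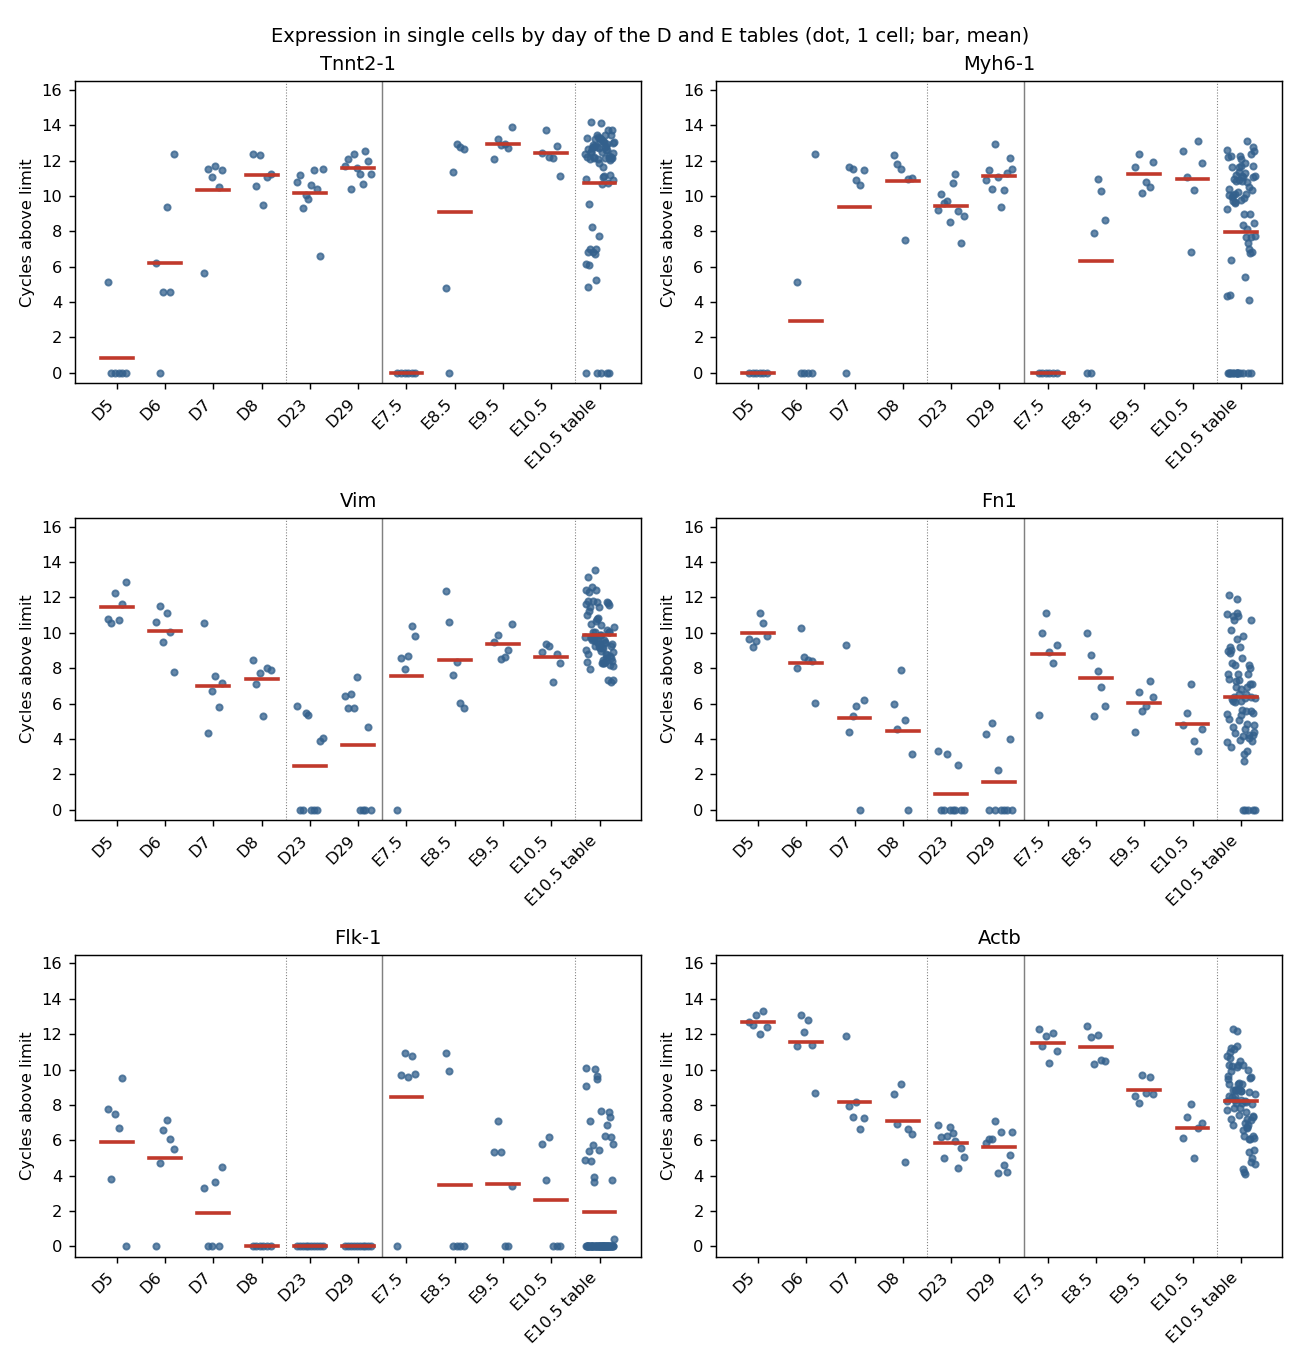
Expression (cycles above the detection limit) of Tnnt2-1, Myh6-1, Vim, Fn1, Flk-1 and Actb in single cells by day of the D tables (left of the solid line) and stage of the E tables (right); each dot is 1 cell and each bar the mean. Tnnt2-1 and Myh6-1 were higher, and Fn1, Flk-1 and Actb lower, at D8 than at D5 and at E10.5 than at E7.5. Relative to Actb, which itself was lower, Fn1 was higher at E10.5 than at E7.5, by 0.84 cycles. Centred on the median detected assay, Fn1 stayed lower (-5.14).

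Cells of the D23-D29 table were set against those of the D5-D8 table to compare late with early days. All 10 cardiomyocyte assays were at least 1 cycle higher in D23-D29 cells: Tnni3-1 averaged 10.05 ± 0.84 (n = 20) against 5.13 ± 4.24 (n = 24), Myh6-1 10.30 ± 1.34 against 5.79 ± 5.64, Myl2 8.5 ± 3.34 against 4.09 ± 4.83 and Tnnt2-1 10.88 ± 1.32 against 7.14 ± 4.88. In detecting cells alone Myh6-1 and Myh6-2 turned to -0.38 and -1.84, and 13 of 24 D5-D8 cells detected Myh6-1. Vim, Fn1, Cnn2 and Sm22A were lower. Vim averaged 3.07 ± 2.95 against 9.0 ± 2.32, Fn1 (fibronectin) 1.22 ± 1.78 against 6.97 ± 3.07, Cnn2 1.72 ± 2.73 against 7.27 ± 2.34 and Sm22A 1.5 ± 1.84 against 6.15 ± 4.16. Flk-1 was detected in 0 of 20 D23-D29 cells, which allows a share of up to 16.8%, and in 13 of 24 D5-D8 cells.

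By list, all 3 fibroblast assays (among them Pdgfra, detected in 0 of 5 FB reference cells) and 2 of the 3 smooth muscle assays were at least 1 cycle lower in D23-D29 cells. Of the 15 assays of progenitor and transcription factors, 2 (both Nkx2.5 assays) were higher and 7 lower, which centring on Actb turned to 5 and 4. Actb itself differed by -4.15 cycles. Nkx2.5-1 averaged 7.33 ± 1.34 against 5.0 ± 4.76, Gata4-2 3.32 ± 2.98 against 6.13 ± 2.22 and Hand2 3.33 ± 2.65 against 5.53 ± 2.15. Hand1 averaged 4.27 ± 2.88 against 7.43 ± 4.49 (0.55 higher after centring on Actb, -3.14 on the median detected assay). Pdgfra averaged 1.03 ± 2.15 against 5.85 ± 3.38. Isl1-2 was detected in 2 of 20 cells against 11 of 24, and Cnn1 in 4 of 20 against 17 of 24. Actb averaged 5.73 ± 0.91 against 9.88 ± 2.73. Pou5f1 was higher in D23-D29 cells, at 5.53 ± 0.47 against 4.05 ± 2.68. Sln was detected in 3 of 20 D23-D29 cells and in 0 of 24 D5-D8 cells.

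In all, 14 assays were higher and 14 lower, and 17 and 10 after centring on Actb, which shifted the median assay by 1.57. Centring on the median detected assay gave 14 and 15. In detecting cells alone 6 were higher, and Nkx2.5-1 and Nkx2.5-2 turned to -1.90 and -1.06. Against the D8 cells alone, 3 assays were higher and 19 lower, with 10 and 9 on Actb and 5 and 17 on the median detected assay. There 7 of the 10 cardiomyocyte assays lay within 1 cycle, 1 was higher and 2 were lower, but 7 were higher and 0 lower on Actb; Tnnt2-1 averaged 10.88 ± 1.32 against 11.18 ± 1.09, a difference of -0.30. Within the D23-D29 table, Gata4-2 averaged 1.32 ± 2.16 on D23 and 5.32 ± 2.28 on D29, Tnnt2-2 9.69 ± 1.07 and 11.56 ± 0.69, and Myh7-2 6.23 ± 4.35 and 4.51 ± 4.23 (SD, n = 10 each), with 16 assays higher and 3 lower on D29. The Ct of the positive control differed by a median of -0.88, D23-D29 minus D5-D8 table. The D5-D8 control repeats that of the reference and E7.5-E10.5 tables in all 42 values, and its material is not given in the sources used here, so whether subtracting it corrects for the run is unknown. With the controls subtracted 23 assays were lower and the differences of Nkx2.5-1 and Nkx2.5-2 turned to -0.40 and -1.09.

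The D5-D8 and E7.5-E10.5 tables set early D cells beside the embryonic stages. Hand1 and Pdgfra were higher in D5-D8 cells: Hand1 averaged 7.43 ± 4.49 against 3.28 ± 4.49 and Pdgfra 5.85 ± 3.38 against 2.14 ± 3.27 (SD, n = 24 each). Isl1-2 was detected in 11 of 24 D cells and 2 of 24 E cells. Vcam1 was detected in 4 of 24 D cells and 15 of 24 E cells, with means of 0.40 ± 0.97 and 3.23 ± 2.76. Myh7-1 averaged 1.80 ± 2.68 in D and 4.71 ± 4.20 in E cells, Nkx2.5-1 5.0 ± 4.76 and 7.52 ± 4.12, and Actn2 4.62 ± 4.23 and 6.99 ± 4.44.

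Of the 10 cardiomyocyte assays 9 were at least 1 cycle lower in D5-D8 cells, with a median difference of -1.41, and 4 after centring on the median detected assay. Myl2 averaged 4.09 ± 4.83 against 5.63 ± 5.25 and Tnnt2-1 7.14 ± 4.88 against 8.61 ± 5.9. Of the 4 endothelial assays 3 were lower, among them Cdh5 (0.26 ± 1.27 against 2.14 ± 4.30). Kit-1 averaged 1.15 ± 1.68 against 2.82 ± 2.86 and Cnn1 5.05 ± 3.90 against 6.82 ± 4.32. Actb averaged 9.88 ± 2.73 and 9.59 ± 2.16. In all, 3 assays were higher and 23 lower in D5-D8 cells. Centring on the median detected assay, which shifted the median assay by 0.50 (Actb, -0.15), gave 7 and 13. There were 14 lower without the E10.5 cells, 15 with a limit 2 cycles stricter, and 1 higher and 13 lower in detecting cells alone. The SDs between cells of Myl2, Actn2 and Tnnt2-1 exceeded their differences in both sets. Days and stages are not matched between these tables, so the differences mix stage with table. In D8 against E10.5 cells (n = 6 each), 3 of 42 assays were higher and 14 lower. There Tnnt2-1 (-1.24), Actn2 (-1.51) and Myh7-1 (-1.32) were lower, while Myh6-1 (-0.10) and Nkx2.5-1 (-0.20) lay within 1 cycle. Myl2 was at 2.38 there, but averaged 9.78 in the 66 other cells of the E10.5 table.

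Against the E7.5-E10.5 cells, the D23-D29 cells had higher means of most contractile assays and lower means of Cnn2, Sm22A, Cnn1, Fn1 and Vim. Tnni3-1 averaged 10.05 ± 0.84 (n = 20) against 6.21 ± 4.42 (n = 24) and Myh6-1 10.30 ± 1.34 against 7.12 ± 5.33, and both were detected in 20 of 20 D23-D29 cells. Cnn2 averaged 1.72 ± 2.73 against 8.38 ± 1.17, Sm22A 1.5 ± 1.84 against 7.21 ± 3.85, Cnn1 1.16 ± 2.43 against 6.82 ± 4.32, Fn1 1.22 ± 1.78 against 6.79 ± 2.10 and Vim 3.07 ± 2.95 against 8.5 ± 2.30. Flk-1 and Kit-1 were detected in 0 of 20 D23-D29 cells and in 14 and 13 of 24 E cells. Kit-2, the other Kit assay, was detected in 4 of 20 D23-D29 cells.

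Of the 10 cardiomyocyte assays 8 were at least 1 cycle higher and 2, those of Myh7, lay within 1 cycle (Myh7-1 4.54 ± 3.65 against 4.71 ± 4.20). In detecting cells alone 6 of those 8 turned, to between -1.48 (Tnnt2-2) and -0.066 (Tnni3-2), and by medians over cells Actn2, Tnnt2-1 and Tnnt2-2 turned to -0.66, -0.99 and -0.97. All 3 fibroblast assays (2 on either centring, with Pdgfra within 1 cycle), 2 of 3 smooth muscle and 3 of 4 endothelial assays (4 on the median detected assay) were lower, as were 7 of the 15 progenitor and transcription factor assays (on Actb, 5 of these 15 were higher and 3 lower), led by Flk-1 and Gata4-2 (3.32 ± 2.98 against 6.54 ± 2.94). Pou5f1 averaged 5.53 ± 0.47 against 3.23 ± 2.51. Vcam1 averaged 0.47 ± 1.19 against 3.23 ± 2.76 and Actb 5.73 ± 0.91 against 9.59 ± 2.16. In all, 9 assays were higher and 18 lower, with 16 and 13 after centring on Actb and 10 and 15 on the median detected assay. The shifts in the median assay were 1.5 on Actb and 0.39 on the median detected assay. Against the E10.5 cells alone, 3 were higher and 22 lower, and 7 of the 9 assays named as higher reversed, among them Tnnt2-1 (-1.54) and Actn2 (-1.55).

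The 66 cells of the E10.5 table that do not recur were compared with the 24 cells of the E7.5-E10.5 table. Myl2 averaged 9.78 ± 5.14 (n = 66) against 5.63 ± 5.25 (n = 24), Myh7-2 8.39 ± 4.27 against 5.54 ± 5.27 and Tnnt2-1 10.56 ± 3.85 against 8.61 ± 5.9. The 24 cells include earlier stages, so these differences mix stage with table. In the 6 E10.5 cells among the 24, Tnnt2-1 averaged 12.42 ± 0.86, above the 66 cells. Myl2 averaged 5.38 ± 6.45 and Myh7-2 5.51 ± 6.06 there, below the 66. Hand2 was detected in 66 of 66 cells against 18 of 24, with means of 6.55 ± 1.38 and 4.81 ± 3.02. Flk-1 was detected in 19 of 66 cells against 14 of 24, with means of 1.90 ± 3.29 and 4.52 ± 4.41, and Kit-1 in 19 of 66 against 13 of 24.

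Of the 10 cardiomyocyte assays 8 were at least 1 cycle higher in the E10.5 table and 2, those of Myh6, lay within 1 cycle (Myh6-1 7.67 ± 4.46 against 7.12 ± 5.33). In the 6 E10.5 cells among the 24, Myh6-1 averaged 10.96 ± 2.25. The count of higher assays therefore does not show a difference between cells of the same stage. Of the 15 progenitor and transcription factor assays, 4 were higher (Hand2, both Gata4 assays, Mef2C-2) and 1 lower (Flk-1). Vim averaged 9.98 ± 1.44 against 8.5 ± 2.30. Cdh5 was detected in 12 of 66 cells and 5 of 24, and all 3 smooth muscle assays lay within 1 cycle, though 2 were higher on Actb. Actb averaged 8.37 ± 1.94 against 9.59 ± 2.16. In all, 13 assays were higher and 3 lower, and 21 and 3 after centring on Actb, which shifted the median assay by 0.92. In detecting cells alone 3 were higher and Tnnt2-1 (-0.74), Tnnt2-2 (-0.88), Myh7-2 (-0.52) and Mef2C-2 (-0.42) turned, and by medians over cells 7 were higher, with Tnnt2-1 at -0.0125.

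Each cell was also assigned to the reference type whose mean profile correlated best with it over the 41 assays other than Actb. With each reference cell left out of its own type's mean, 30 of 30 returned to their type (100%, 95% interval 88.4% to 100%). Of the D5 and of the D6 cells, 5 of 6 were nearest to CPC; 5 of 6 D7 cells and 6 of 6 D8 cells were nearest to CM. All 20 D23-D29, all 15 atrial and all 15 ventricular cells were nearest to CM, with median correlations across assays of 0.893, 0.673 and 0.880. Since 2 of the 5 CM reference cells are themselves D29 cells, the D23-D29 cells were partly matched to their own set; with those 2 left out, all 20 were still nearest to CM, and the median correlations were 0.892, 0.662 and 0.874. At E7.5, 3 of 6 cells were nearest to EDC, 2 to CPC and 1 to FB; at E8.5, 4 were nearest to CM and 2 to EDC; all 12 cells of E9.5 and E10.5 in that table were nearest to CM. In the E10.5 table, 56 of 72 cells (77.8%, 66.4% to 86.7%) were nearest to CM, 8 (11.1%, 4.92% to 20.7%) to FB, 7 (9.72%, 4.0% to 19%) to EDC and 1 to CPC. No cell outside the reference was nearest to ES. Every cell is given its best match among 6 types, however low the correlation.

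**Figure D4:**
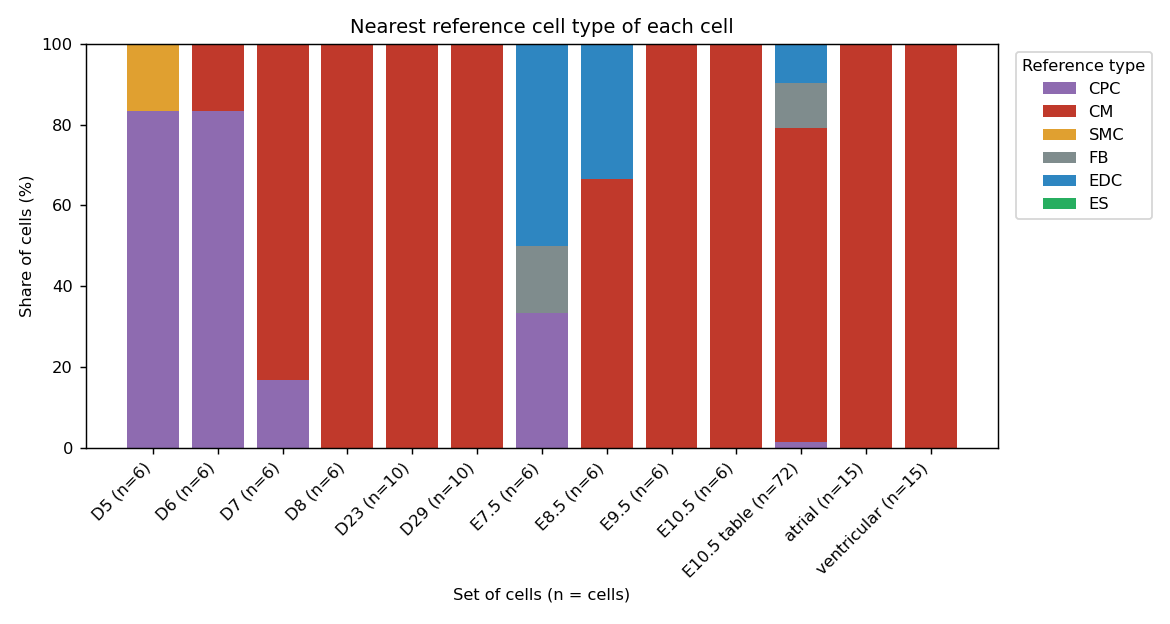
Share of cells (%) in each set whose profile correlated best with each of the 6 reference types (colours; n, number of cells). D5 and D6 cells were mostly nearest to CPC (83.3% each) and all D8, D23 and D29 cells to CM, while the E10.5 table held 77.8% of cells nearest to CM.

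Assays of more than 1 lineage list were often detected in single cells. A cardiomyocyte and a smooth muscle assay were both detected in 22 of 24 D5-D8 cells (91.7%, 73% to 99%), 15 of 20 D23-D29 cells (75%, 50.9% to 91.3%), 66 of 72 cells of the E10.5 table (91.7%, 82.7% to 96.9%), 9 of 15 atrial and 7 of 15 ventricular cells. Requiring 2 assays of each list left this pair in 58.3% of D5-D8, 15% of D23-D29, 77.8% of E10.5-table and 6.67% of ventricular cells, and a limit 2 cycles stricter left it in 40% of D23-D29 cells. A cardiomyocyte and an endothelial assay were both detected in 13 of 24 D5-D8 cells (54.2%, 32.8% to 74.4%), 0 of 20 D23-D29 cells (up to 16.8%) and 32 of 72 E10.5 cells (44.4%, 32.7% to 56.6%). In D5-D8 cells it rested mostly on Flk-1, which the progenitor list also holds: Flk-1 was detected in 13 of 24 cells, Cdh5 and Pecam1 in 1 each and Vwf in 0. The 2-assay requirement left the cardiomyocyte and endothelial pair in 4.17% of D5-D8 cells and 11.1% of E10.5 cells. The CM reference cells, of which 2 are D29 cells, gave a background: 4 of 5 detected a smooth muscle assay (Sm22A at a mean of 0.86 ± 0.65) and 0 of 5 an endothelial one. All 5 SMC and all 5 FB cells detected Sm22A, 3 of 5 SMC cells detected Actn2 and 2 of 5 FB cells Myl2. In the heart cells Flk-1 was detected in 5 of 15 atrial and 5 of 15 ventricular cells. Co-detection alone therefore does not show a cell of 2 lineages. Cdh5, Pecam1 and Vwf were detected together in 7 of 72 cells of the E10.5 table (9.72%, 4.0% to 19%).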

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

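The tests of explanations in this part, for the assays that were lower in D23-D29 than in D8 cells, were chosen after the results were seen, as was the simulation; the rule for single cells far from the others was set before.

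Single cells stood apart from their set in 4 of the 40 groups of values examined (20 sets, each for the number of detected assays and for Actb), and chance gives such a cell in about 1 in 20 groups. Simulated normal values with each set's mean and SD gave one in 5.16% of groups for Actb and 6.52% for the number of assays, rounded to whole assays, or 2.34 of the 40 groups. In the CM reference cells, CM-3 had Actb at 7.284 cycles above the detection limit, against 5.93 to 6.14 in the other 4. Among the D7 cells, D7-1 had Actb at 11.894, against 6.63 to 8.15 in the other 5. EDC-4 detected 15 assays and the other EDC cells 11 to 12. E9.5-1 detected 34 assays and the other E9.5 cells 28 to 30.

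The positive control columns enter the comparisons of cells only in the alternative that subtracts them, and held signals of their own. Of the positive control's values in the atrial table, 40 equalled values that stand 1 row higher in the reference table, and 40 did so in the ventricular table. The positive control of the D23-D29 table differed from that of the reference table by a median Ct of -0.879, with 38 of 42 assays earlier.

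Vim, Fn1, Cnn1, Cnn2 and Sm22A, picked from 19 lower assays, were lower in D23-D29 than in D8 cells by a median of -4.34 cycles (-5.25 to -2.56), but Gata4-2 (-3.73), Hand2 (-3.0), Mef2C-2 (-2.64), Nkx2.5-1 (-1.86) and Actb (-1.36) were lower too, and relative to Actb Sm22A was at -1.24. Less template per cell, or a run less sensitive for all assays, would as the whole cause lower every assay that all cells detect by about as much. Assays nearer the limit would lose more, since an undetected cell counts as 0. The 7 assays of Actn2, Myh6, Tnni3 and Tnnt2, detected in every cell of both sets, differed by a median of -0.041 cycles (-1.52 to 1.35). All 7 lay above the 5 as measured, but most of the 5 differed less in detecting cells alone. There Cnn2 averaged 5.74 against 6.97, Cnn1 5.82 against 7.53, Vim 5.58 against 7.40, Fn1 3.48 against 5.32 and Sm22A 2.14 against 4.88. Other cell types among the D8 cells would leave some without contractile assays, but 100% of the 6 D8 cells (54.1% to 100%) detected Tnnt2-1 and Myh6-1. That covers the cells measured, and with so few it does not exclude other types among D8 cells at large. A run less sensitive for these 5 assays cannot be told apart from lower expression: the D23-D29 positive control differed by a median Ct of -1.016 over the 5, but the D5-D8 control repeats the reading of the reference and E7.5-E10.5 tables in all 42 values and its material is not given, so it need not come from the D5-D8 run. Lower expression of these 5 genes on later days, a different choice of cells at sorting, and less template together with higher contractile expression stay open and were not tested.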

How the results depend on the processing

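Chosen after the data were seen were single ages, days or stages, all 72 E10.5 cells, leaving out the E10.5 cells, a CM reference without the repeated cells, and values relative to the positive control; the other alternatives were planned. Without low-quality cells, 88 single assays and 10 counts of assays moved by less than the SD between cells or 1.5 times, as did 15 and 2 with all 72 E10.5 cells. The share nearest to CM stayed within its counting interval in all 6 tables under Spearman correlation, Euclidean distance, detection alone and the CM reference without the repeated cells. Of the single assays named in the comparisons of tables, 71 moved by less than the SD, 16 by more and 1 reversed when centred on Actb, 86 by less and 2 by more both when centred on the median detected assay and with the stricter limit, 74 by less, 8 by more and 6 reversed as medians, and 54 by less, 4 by more and 17 reversed in detecting cells alone. Depth is set by the detection limit and by 5 to 72 cells per set. No paired analysis was possible because no label pairs cells between sets.

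Means over detecting cells leave the undetected ones out by construction. Atrial minus ventricular, they gave 4 assays higher and 2 lower, and reversed Cnn2 (-0.62), Gata4-1 (0.395) and Mef2C-2 (-0.76). D23-D29 minus D5-D8, they gave 6 higher and reversed Myh6-1 (-0.38), Myh6-2 (-1.84), Nkx2.5-1 (-1.90) and Nkx2.5-2 (-1.06). D5-D8 minus E7.5-E10.5, they gave 1 higher and 13 lower. D23-D29 minus E7.5-E10.5, they gave 2 higher and reversed Actn2 (-0.73), Myh6-1 (-0.38), Myh6-2 (-0.83), Tnni3-2 (-0.066), Tnnt2-1 (-1.28) and Tnnt2-2 (-1.48). For the E10.5 minus the E7.5-E10.5 table, they gave 3 higher and reversed Mef2C-2 (-0.42), Myh7-2 (-0.52), Tnnt2-1 (-0.74) and Tnnt2-2 (-0.88).

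Medians over cells gave 3 assays higher in atrial cells and reversed Mef2C-2 (-0.63), and reversed Nkx2.5-1 (-0.011) in D23-D29 minus D5-D8. In D23-D29 minus E7.5-E10.5 they gave 4 higher and reversed Actn2 (-0.66), Tnnt2-1 (-0.99) and Tnnt2-2 (-0.97), and 7 higher for the E10.5 table, with Tnnt2-1 at -0.0125; the cause was not tested. Centred on Actb, 10 assays were lower in atrial cells, Hand1 reversed to 0.55 in D23-D29 minus D5-D8, 16 were higher in D23-D29 than in E7.5-E10.5 cells, 21 higher in the E10.5 table, 11 higher in CPC, 4 lower on D8 than on D5 and 13 higher in adult than in neonatal atrial cells; the cause was not tested. Centred on the median detected assay, 7 were higher and 13 lower in D5-D8 minus E7.5-E10.5; the cause was not tested. A limit 2 cycles stricter, which detects less by construction, gave 3 higher in atrial cells, 15 lower in D5-D8 minus E7.5-E10.5, and a cardiomyocyte with a smooth muscle assay in 40% of D23-D29 cells.

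Requiring at least 2 assays of each list, stricter by construction, left a cardiomyocyte and smooth muscle pair in 58.3% of D5-D8, 15% of D23-D29, 77.8% of E10.5-table and 6.67% of ventricular cells. It left a cardiomyocyte and endothelial pair in 4.17% of D5-D8, 4.17% of E7.5-E10.5, 11.1% of E10.5-table and 0% of atrial cells.

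The next alternatives compare other cells by construction. Adult cells alone gave 2 higher and 10 lower in atrial cells and reversed Sm22A (-0.075), and neonatal cells alone gave 15 higher and reversed Gata4-1 (0.80), Hand2 (1.15) and Tnnt2-2 (0.21). Against D8 cells only, 3 assays were higher in D23-D29 cells, and Actn2 (-0.041), Hand1 (0.69), Myh6-1 (-0.56), Myh6-2 (-1.52), Myh7-2 (-1.13), Nkx2.5-1 (-1.86), Nkx2.5-2 (-1.35) and Tnnt2-1 (-0.30) reversed. Against E10.5 cells only, 3 were higher in D23-D29 cells, and Actn2 (-1.55), Myh6-1 (-0.66), Myh6-2 (-1.12), Tnni3-1 (-0.10), Tnni3-2 (-1.39), Tnnt2-1 (-1.54) and Tnnt2-2 (-1.62) reversed. Without the E10.5 cells, 14 were lower in D5-D8 minus E7.5-E10.5. Relative to the positive control, 23 were lower in D23-D29 minus D5-D8, and Nkx2.5-1 (-0.40) and Nkx2.5-2 (-1.09) reversed; the D5-D8 control is the same reading as in the reference and E7.5-E10.5 tables, so whether this corrects for the run is unknown, and the cause was not tested.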

Other observations

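The tests of explanations in this part, for Pou5f1 and Sox2 and for the sample titles, were chosen after the results were seen, as were the assays named here.

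Among single cells of the E10.5 table Sln, an atrial assay, was rare and Myl2, a ventricular one, was common. Myl2 without Sln was detected in 57 of 72 cells (79.2%, 68% to 87.8%), Sln without Myl2 in 3 and both in 2 (2.78%, 0.338% to 9.68%), while 10 cells detected neither. With so few Sln cells, whether the assays exclude each other was not tested. Sln was found in 4 of the 6 cells that recur in the E7.5-E10.5 table (66.7%, 22.3% to 95.7%) and in 1 of the 66 others (1.52%, 0.0384% to 8.16%), which also detected Myl2. Myl2 was found in 3 of those 6 and in 56 of the 66. Cdh5, an endothelial cadherin, was detected together with Tnnt2-1 in 7 of the 72 cells and without it in 5.

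For 9 genes a pair of assays read the same cells. Over all distinct cells both assays gave the same call, detected or not, in 97.4% of cells for Myh6, 96.4% for Nkx2.5 and for Tnnt2 and 95.8% for Tnni3. The calls for Kit, a receptor tyrosine kinase, were the same in 60.9% of cells (53.7% to 67.9%), with 36 cells detected by assay 1 alone and 39 by assay 2 alone. Gata4 was detected by assay 2 alone in 50 cells and by assay 1 alone in 2. Isl1 was detected by assay 2 alone in 18 cells and by both in 3. Where both detected, assay 2 minus assay 1 averaged 2.11 ± 0.93 cycles for Gata4 and -2.51 ± 0.76 for Nkx2.5 (SD between cells).

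Pou5f1 was detected in 88.2% of the distinct cells other than ES (82.7% to 92.5%) at a median of 5.0 cycles, against 9.19 in the ES cells, and Sox2 in 47.1% (39.7% to 54.5%) at 3.38, against 5.24. Template in the reagents would give signal in the negative controls, and 0 of the 6 had any for Pou5f1 or Sox2. These 6 need not be separate readings, since the positive control beside them repeats between tables, and the E10.5 table holds none. Origin from ES cells as the whole cause would spare heart cells, and Pou5f1 was detected in 90% of the 30 atrial and ventricular cells (73.5% to 97.9%). Genomic DNA, a near constant amount per cell, is argued against as the whole source for Pou5f1, whose set medians differed by 4.88 cycles (7.51 in SMC, 2.63 in D8 cells). The D8 median rests on 3 detecting cells. Several other sets lay close together, at 5.20 in CPC, 5.21 in CM, 5.11 in EDC and 5.30 in D29 cells. Genomic DNA as part of the Pou5f1 signal is therefore not excluded. For Sox2 the set medians differed by 3.663 cycles over 12 sets, which lies between the bounds set for and against genomic DNA, so this source cannot be told apart from transcript. Transcripts of related sequences read by the assays, and low expression of these genes, may account for the signal and were not tested.

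Sample titles and table names disagree on the origin of the D5-D8 and E7.5-E10.5 cells. That every title is right is argued against by 6 cells with identical values under a title of ES-derived cells and under one of embryo cells. Table and cell names held together: 0 of 140 cells in the tables named by day or stage had a name outside their table's range. This count does not exclude a fault common to both names.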
